A study of Rattus norvegicus with 16 samples.

How the data were processed

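Gene expression was measured in livers of male Sprague-Dawley rat pups at 21 days of age on 16 Agilent rat arrays with 2 colours. On every array the liver RNA was labelled with Cy5 and a universal rat reference RNA with Cy3, so each value compares a liver with the same reference. Per the labels, each array held RNA pooled at random from 2 pups of a group, which makes 8 pups and 4 arrays per group. The dams, and through them the pups, received corn oil (C), a mixture of organochlorine pesticides, polychlorinated biphenyls and methylmercury at 0.5 mg/kg/day (0.5M) or 1.0 mg/kg/day (M), or a mixture of aryl hydrocarbon receptor agonists at 1.8 ng/kg/day in dioxin equivalents (AhR). The arrays lay on 2 slides with 2 arrays of every group on each: replicates 1 and 2 on slide 1, replicates 3 and 4 on slide 2. The labels do not say which pups shared a litter. As the dams were dosed and the 4 arrays of a group are treated as independent, standard errors and p-values would be too small if arrays shared litters.

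The deposited scan files, 1 per array, were written by Agilent Feature Extraction 10.7.3.1 and hold for 62976 spots the median signal and the median background of both channels as scanner intensity. Per the file headers, the LogRatio column of these files is on the log10 scale and the quality marks of the spots, of the unit other, are 0 or 1. The authors also deposited a value table on the log2 scale. Set against the scan files, it holds the ratio of Cy5 to Cy3 without background subtraction and after a correction for intensity, with a correlation across probes of 0.977 to 0.998 between each array and its own scan file and of at most 0.878 with any other. All main values were computed from the scan files. The plan named mean signals, but the files hold medians, so the medians were used.

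Signals were background-corrected with the normexp method of limma 3.58.1 (offset 50) and normalized by loess within each array, with control spots given no weight. Spots that the scanner software marked as non-uniform or as a population outlier were left out, and the remaining spots of a probe were averaged. A probe was kept when the software marked it well above background in Cy5 on at least 4 of the 16 arrays. Of 30367 probes, 14524 passed this filter, and 12 of these were left out for missing values. Probes were given gene symbols through their RefSeq transcript numbers (18004 probes with a symbol, 12363 without). Of several probes of a gene the brightest was used, which left 13146 transcripts, 8562 of them with a symbol. No coordinates are given, as the name table was used for symbols alone. Cyp2b1 has no entry in the name table, and Ahrr and Cyp3a9 did not pass the filter.

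Differences between groups were tested with limma (lmFit, contrasts.fit and eBayes) on the log2 ratios of all 16 arrays in a single model with a mean per group and a term for the slide. Where a probe was not well above background on any array of a group, its fold is a bound for the dim signal. Such a bound is an estimate that takes no account of the spread between arrays. The bound compares the mean Cy5 signal of the brighter group, after loess and Aquantile, with the higher of the dim signal and the lowest signal well above background on each array. It is open to dye bias, as no dyes were swapped, and where the fold of the ratio was smaller, that is given as the bound. The tests were two-sided and adjusted by the Benjamini-Hochberg method over the 13146 transcripts within each of 6 pairwise comparisons, with a threshold of 0.05. A moderated F-test over the 4 groups and a contrast for departure from a straight line over the doses came from the same model. "Higher in 4 of 4 arrays" means that the arrays of the first group lay above the highest array of the other group. The 28 gene lists were tested with camera of limma (preset correlation between genes of 0.01), adjusted over the 28 lists within each comparison, and again with an estimated correlation and with fry. A list is said to be called when it passed by camera with the preset correlation, unless another test is named. In fry, the directional test asks whether the genes of a list move one way on balance and the mixed test whether they change in either direction, and neither compares a list with other genes. The computations used R 4.3.3 and the data.table package (version 1.17.8).

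The model, the comparisons, the gene lists, the rule for naming genes and most alternatives were chosen before the data were examined. The rule takes, for each comparison with C, the 8 largest rises and the 8 largest falls with a gene symbol among transcripts past the threshold, or, where fewer than 10 passed, also the 10 with the smallest unadjusted p. It adds Cyp1a1, Cyp1a2, Cyp1b1, Ahrr, Nqo1, Cyp2b1, Cyp2b2, Cyp3a1 (here Cyp3a23-3a1), Cyp3a9 and Abcc3 everywhere, and from each list up to 3 members past the threshold or else the member with the smallest p. Between exposed groups it takes 4 and 4 in place of 8 and 8 and leaves the lists out. The 13 further genes with a symbol that passed in M against C were chosen after their values were seen.

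The alternatives were other background corrections, normalizations, filters and weights, the slide left out, the replicate number as a block, the value table of the authors, each slide alone, each array left out in turn, and other thresholds. Leaving out arrays with transcripts of other tissues, the list tests within each slide, and the alternatives and simulations for the dose and the alternatives for the shared responses were chosen after seeing the data. The replicate number recurs in every group and is not a block in the main model. Once the slide was accounted for, arrays of different groups with the same number correlated above 0.1 in 4 of 24 pairs. Their median was 0.00205, against -0.126 for other numbers on the same slide. Removing group and slide means lowers correlations within a slide, so a pairing by number is not ruled out. The pipeline was tested on simulated data with independent normal noise, at the variance that the model of all 16 arrays gave each transcript. Correlation between genes was not simulated, so real arrays may give other counts. Of 50 changed genes per size it recovered 31 at a log2 difference of 0.5, 48 at 1 and 50 at 2, with 10 false calls among 12946 unchanged genes. The series also describes adult rats, cross-fostered groups and a combined exposure group. None of the 16 arrays belongs to them.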

Results

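Liver transcripts were measured in 4 groups of 21-day-old male rats, with 4 arrays of 2 pooled pups each. C pups were unexposed. The dams of 0.5M and M pups were given a lower or a higher dose of a mixture of organochlorine pesticides, polychlorinated biphenyls and methylmercury. The dams of AhR pups were given dioxin-like compounds that activate the aryl hydrocarbon receptor. Between 7082 and 13824 of 30367 probes per array stood well above background in the liver channel on slide 1, and between 13006 and 15686 on slide 2. On no array was a probe marked saturated in at least 50% of its spots in either channel, control probes left aside. The median standard error of a log2 difference between groups was 0.104, and the number of arrays limits the precision. Between the 2 slides 1053 transcripts differed, and as each slide holds 2 arrays of each group, the slide is a term of the model. The slides held different pups, so effects of slide and of pups cannot be told apart. Across the 4 groups, 23 transcripts differed by the moderated F-test of limma (11 without M 3 or without M 4).

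Some arrays also held transcripts that liver hardly makes. Skeletal muscle transcripts were high in M 2 and 0.5M 4, where 23 of 24 markers lay above all 14 other arrays, with a median log2 difference of 4.62. Transcripts of the exocrine pancreas were high in M 1 and AhR 2 (9 of 12 markers, median log2 difference 0.86), and fat transcripts in C 2 (6 of 6 markers, 1.13). Some values below were also computed without these 5 arrays. This left M 3 and M 4 in M, both on slide 2, so differences of M then rest on a slide term estimated from the other groups.

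**Figure D1:**
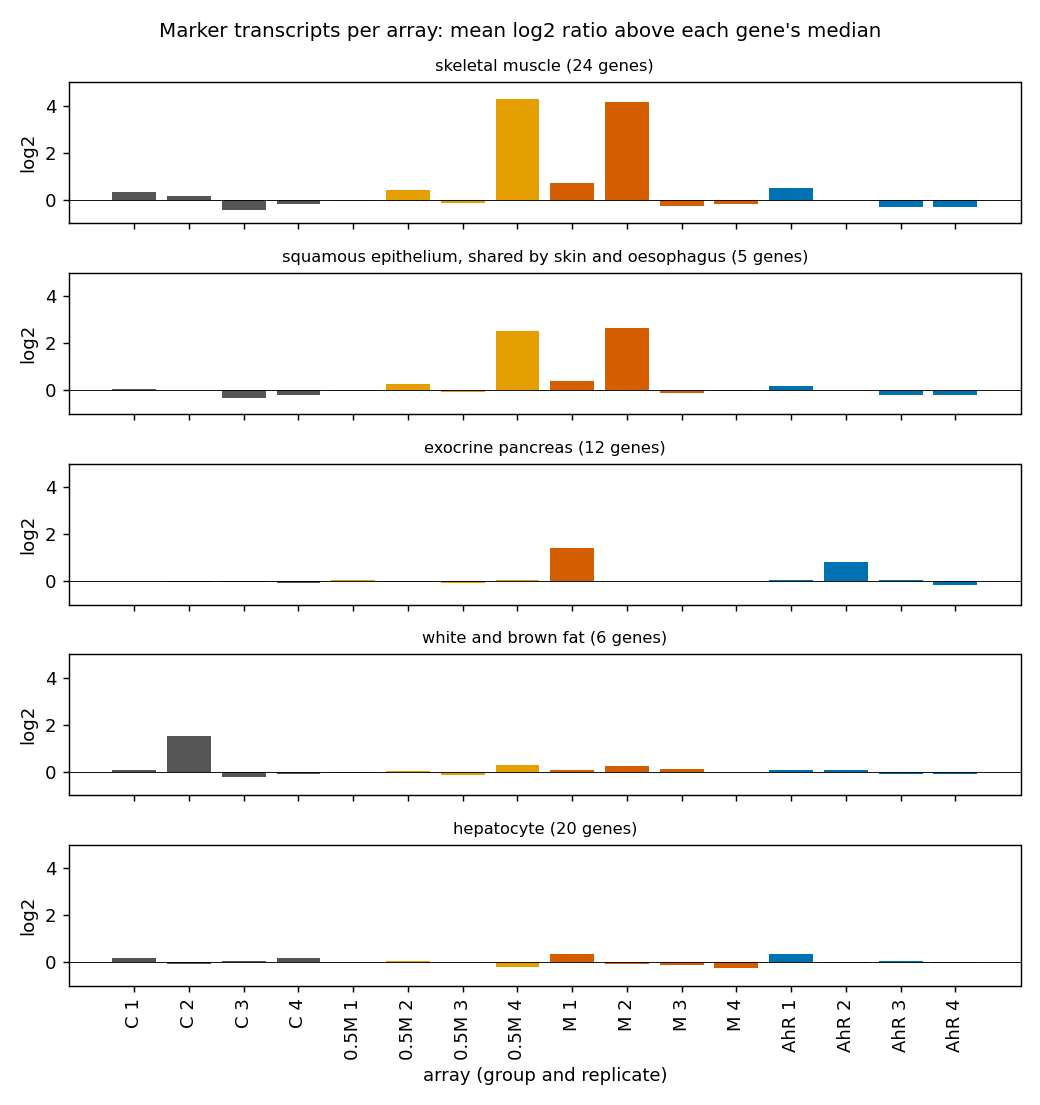
Mean log2 ratio of marker transcripts of 5 tissues on each array, above each gene's median over the 16 arrays; each bar is an array and its colour the group. The skeletal muscle bars reach 4.14 in M 2 and 4.28 in 0.5M 4, the pancreas bars 1.39 in M 1 and 0.80 in AhR 2, and the fat bar 1.54 in C 2.

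M against C asks what the higher dose of the mixture did to the liver of the pups. Cyp1a1 (NM_012540), the P450 most closely tied to the aryl hydrocarbon receptor, rose 23.9-fold (log2 difference 4.58 ± 0.18, SE, n = 4 arrays per group, adjusted p = 6.5e-10). Cyp2b2 (NM_001198676), a P450 induced by phenobarbital, rose 8.91-fold (3.16 ± 0.22, adjusted p = 1.2e-06). Another of its probes gave a smaller log2 difference of 2.02. Cyp1a2, another P450 under the aryl hydrocarbon receptor, rose 3.39-fold (1.76 ± 0.17, adjusted p = 3.6e-05), and Cyp2c6v1, a P450 that phenobarbital-like compounds also induce, 3.63-fold (1.86 ± 0.17, adjusted p = 3.6e-05). Each was higher in 4 of 4 M arrays. Of 13146 transcripts, 34 were higher and 8 lower in M than in C. Of these 42, 40 had groups that did not overlap, which choosing them by their difference on the same arrays favours.

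Ceacam4, of a family of cell adhesion molecules, rose 5.28-fold (log2 2.40 ± 0.18, adjusted p = 2.1e-06) and stood well above background on 3 of the 4 C arrays. Cyp2c7, a P450 with higher levels in female than male liver, rose 3.77-fold (1.91 ± 0.20, adjusted p = 1.2e-04). Aldh1a1, which oxidises retinal to retinoic acid, rose 3.58-fold (1.84 ± 0.28, adjusted p = 0.00673) and Apoa2, a protein of high-density lipoprotein, 2.84-fold (1.504 ± 0.26, adjusted p = 0.0162). The falls were smaller. The protease inhibitor A2m, an acute phase protein of the rat, fell by 1.04 ± 0.16 on the log2 scale (2.05-fold, adjusted p = 0.00721). Cyp17a1, a P450 of steroid synthesis, fell by 0.85 ± 0.13 (adjusted p = 0.00721) and the carrier gene Slc16a11 by 0.66 ± 0.10 (adjusted p = 0.00673). The phosphate carrier Slc34a2, well above background on 2 of the 4 M arrays, fell by 0.57 ± 0.11 (adjusted p = 0.0402). Every gene with a symbol that passed in M against C (30 of the 42 transcripts) had all 4 M arrays beyond all 4 C arrays, which the choice by the same arrays favours.

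**Figure D2:**
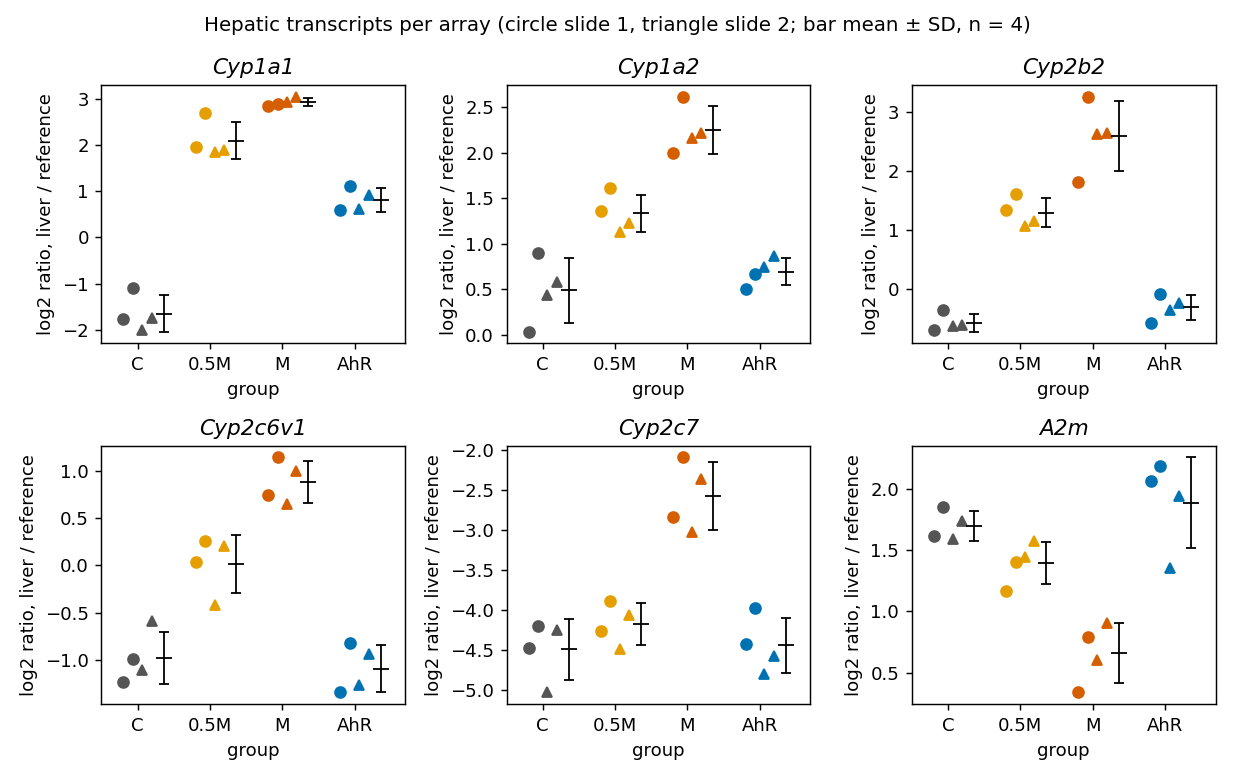
Log2 ratio of liver to reference RNA for 6 genes in each group (point, array; circle, slide 1; triangle, slide 2; bar, mean ± SD, n = 4). Cyp1a1 averaged -1.65 in C, 2.10 in 0.5M, 2.93 in M and 0.81 in AhR, while Cyp2b2 averaged -0.57 in C and -0.30 in AhR.

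By gene list, 4 of 10 measured targets of the aryl hydrocarbon receptor rose in M. Beside Cyp1a1 and Cyp1a2 these were the glucuronosyltransferase Ugt1a6 (2.15-fold, log2 1.10 ± 0.14, adjusted p = 6.6e-04) and the P450 Cyp1b1 (0.77 ± 0.16, adjusted p = 0.0497). No C array had Cyp1b1 well above background. Its estimated rise was 1.71-fold, a bound in regard to the dim C signal and not to the spread between arrays. Adjusted over the list alone 6 passed, 9 of the 10 were higher in M, the median log2 difference was 0.58, and camera called the list (adjusted p = 9.5e-14). The quinone reductase Nqo1 did not pass over all transcripts (log2 0.89, adjusted p = 0.0710, higher in 4 of 4 arrays). CAR and PXR are the receptors through which phenobarbital-like compounds act. Of their 17 measured targets 5 rose, namely Cyp2b2, Cyp2c6v1, Aldh1a1, the glucuronosyltransferase Ugt2b1 and the P450 Cyp3a23-3a1. Cyp3a23-3a1 rose 2.12-fold (1.08 ± 0.17, adjusted p = 0.00721). Adjusted over the list alone 13 passed. The list's median was 0.68 with 15 of 17 members higher (adjusted p = 2.2e-19). The efflux pump Abcc3 stood at 0.44 (adjusted p = 0.270, higher in 2 of 4 arrays). Both lists kept their calls with an estimated correlation (adjusted p = 2.9e-04 and 6.9e-04).

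Of 17 measured targets of NRF2, the regulator of the antioxidant response, 2 glutathione transferases rose: Gsta3 (1.89-fold, log2 0.92 ± 0.17, adjusted p = 0.0264) and Gsta4 (1.72-fold, 0.78 ± 0.13, adjusted p = 0.0105). Adjusted over the list alone 3 passed, and the list was called with a median of 0.25 (adjusted p = 1.3e-06; adjusted p = 0.116 with an estimated correlation). Markers of periportal hepatocytes were lower in M, with 9 of 10 members below C and a median of -0.22 (adjusted p = 0.00126; adjusted p = 0.116 with an estimated correlation). None passed over all transcripts and 1 passed adjusted over the list alone. Its member with the smallest p, the aldehyde dehydrogenase Aldh1b1, stood at -0.56 (adjusted p = 0.141). Acute phase genes were lower, with A2m the member that fell, 2 adjusted over the list alone and a median of -0.09 (adjusted p = 0.0271; adjusted p = 0.753 with an estimated correlation). Of 9 measured genes with higher levels in female liver, Cyp2c7 rose and Cyp17a1 fell, and 5 passed adjusted over the list alone. The median and mean of this list differed in sign (-0.04 and 0.17, adjusted p = 0.965). Camera called none of the other 22 lists in M against C either (adjusted p of all 23 from 0.101 to 0.965), and 3 of the 23, among them bile acid and female-biased genes, were called by the mixed test of fry. Among their members with the smallest p, the sulfotransferase Sult1b1 of the thyroid list stood at 1.22 and the clock repressor Nfil3 at -0.64 ± 0.14 (adjusted p = 0.0641 each). The fatty acid dehydrogenase Acadvl stood at -0.34 (adjusted p = 0.0991) and the triglyceride synthesis enzyme Dgat2 at -0.39 (adjusted p = 0.120). Stellate cell and fibroblast markers had a median of 0.40 (adjusted p = 0.129), and 0.04 without M 2 and 0.5M 4.

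**Figure D3:**
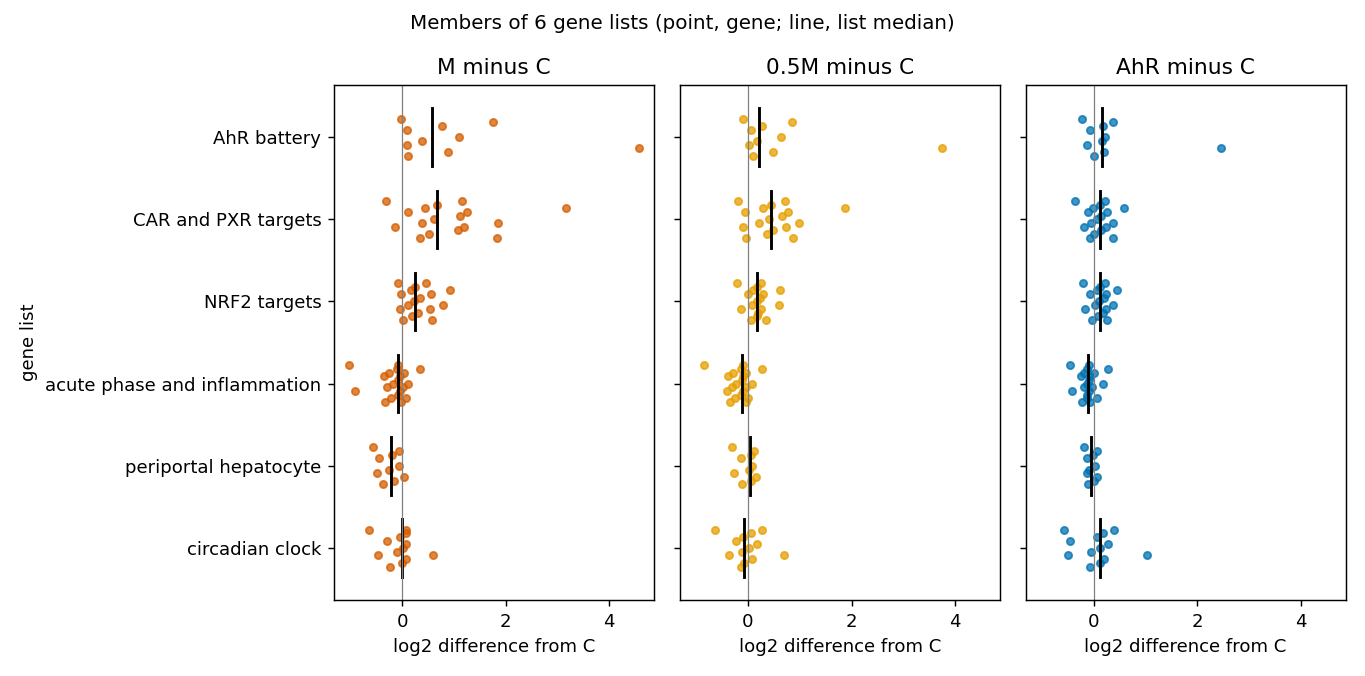
Log2 difference from C for the measured members of 6 gene lists in M, 0.5M and AhR (point, gene; black line, list median). The median of the CAR and PXR targets was 0.68 in M, 0.45 in 0.5M and 0.13 in AhR.

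Within slide 1 and within slide 2, the log2 difference between M and C was 4.30 and 4.87 for Cyp1a1, 3.06 and 3.25 for Cyp2b2, 1.84 and 1.68 for Cyp1a2, 2.05 and 1.67 for Cyp2c6v1 and 1.97 and 2.83 for Ceacam4. It was 1.88 and 1.95 for Cyp2c7, -1.17 and -0.91 for A2m and 0.30 and 1.24 for Cyp1b1. The median of the aryl hydrocarbon receptor targets was 0.33 and 0.66, and that of the CAR and PXR targets 0.71 and 0.73. Slide 1 alone ended the calls of periportal and acute phase genes (adjusted p = 0.533 each), and without M 2 and 0.5M 4 that of acute phase genes ended too (0.207). Medians moved to 0.16 for NRF2 targets on slide 1, to -0.37 for periportal genes on slide 2 (-0.35 without M 2 and 0.5M 4) and to -0.20 for acute phase genes on slide 2 (-0.24 without the 5 arrays with other tissue, -0.19 without M 1 and AhR 2). The count of 42 became 41 with the replicate number as a block, 1 with median centring in place of loess, 4 on slide 1 alone, 7 on slide 2 alone, 20 with the scanner's own ratios and 66 with array weights, and it was 22 without C 4 or without M 3, 25 without C 1 and 27 without M 1. Leaving out 1 array ended the calls of Gsta4 (without C 4, adjusted p = 0.0631), Apoa2 (C 1, M 1, M 3 or C 4, up to 0.0796), Gsta3 (M 1, M 3, M 4 or C 4, up to 0.108), Slc34a2 (6 of 8 arrays, all but C 1 and M 1, up to 0.182) and Cyp1b1 (7 of 8, all but M 1, up to 0.222). It let Nqo1 (M 2, adjusted p = 0.0373), Sult1b1 (C 3, 0.0244) and Dgat2 (C 2, 0.0387) pass. Without the 5 arrays with other tissue, which left M 3 and M 4 in M, 29 transcripts passed. Fewer arrays and other tissue cannot be told apart as reasons for calls lost there. Aldh1a1 (1.82, adjusted p = 0.0661), Apoa2 (1.62, 0.0515), A2m (-0.87, 0.142), Slc16a11 (-0.63, 0.0620), Cyp3a23-3a1 (1.16, 0.0593) and Gsta3 (0.90, 0.104) were no longer called.

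0.5M against C asks the same of the lower dose. Cyp1a1 rose 13.4-fold (log2 3.74 ± 0.18, n = 4 arrays per group, adjusted p = 1.4e-08) and Cyp2b2 3.65-fold (1.87 ± 0.22, adjusted p = 0.00181), each higher in 4 of 4 arrays. Another probe of Cyp2b2 gave a smaller log2 difference of 1.21. No other transcript passed, and none was lower by the test of limma (858 at an unadjusted p under 0.05, against 657.3 by chance). Among the genes that lay above all C arrays in 4 of 4 0.5M arrays without passing were Cyp2c6v1 (0.99, adjusted p = 0.154), the electron carrier Cyb5a (0.56, adjusted p = 0.195), Cyp1a2 (0.85, adjusted p = 0.268), Ugt1a6 (0.65, adjusted p = 0.390) and the bile pump Abcc2 (0.49, adjusted p = 0.471). Cyp3a23-3a1 (0.45, adjusted p = 0.699), Nqo1 (0.48, adjusted p = 0.738), Abcc3 (0.37, adjusted p = 0.725) and Cyp1b1 (0.17, adjusted p = 0.853) did not pass. Of the remaining small p-values, the deubiquitinase Usp42 stood at -0.46 (adjusted p = 0.195), and the transcription factor Patz1 and Nfil3 at -0.42 and -0.63 (adjusted p = 0.390 each), all below every C array.

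Targets of the aryl hydrocarbon receptor were higher in 0.5M as a list (1 of 10 passed over all transcripts, 3 adjusted over the list alone, median 0.22, adjusted p = 2.9e-08), and so were CAR and PXR targets (1 of 17, 8 adjusted over the list alone, median 0.45, adjusted p = 1.8e-10). Both kept their calls with an estimated correlation (adjusted p = 0.00306 and 0.00902). The other 6 called lists lost their calls with it, and none of their members passed over all transcripts. Higher in 0.5M were cholesterol synthesis genes (22 of 23 members, median 0.18, adjusted p = 2.1e-04; adjusted p = 0.542 with an estimated correlation), fatty acid synthesis genes (12 of 16, 0.14, adjusted p = 0.00395; 0.436 with it) and NRF2 targets (14 of 17, 0.18, adjusted p = 3.7e-04; 0.322 with it). Lower were PPARa and fatty acid oxidation genes (19 of 27 members, -0.10, adjusted p = 0.00344; 0.322 with it), acute phase genes (18 of 20, -0.12, adjusted p = 0.00527; 0.506 with it) and pericentral hepatocyte genes (8 of 9, -0.19, adjusted p = 0.00527; 0.322 with it). Members with the smallest p in these lists were Me1, which makes NADPH for fat synthesis (0.88, adjusted p = 0.578), Msmo1 of cholesterol synthesis (0.65, adjusted p = 0.657), the endotoxin-binding protein Lbp (-0.85, adjusted p = 0.578) and the P450 Cyp2e1 (-0.62, adjusted p = 0.621). Camera did not call the other 20 lists (adjusted p 0.233 to 0.993).

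Within slide 1 and slide 2 the difference between 0.5M and C was 3.75 and 3.74 for Cyp1a1 and 2.005 and 1.73 for Cyp2b2, and the median of the CAR and PXR targets was 0.55 and 0.39. That of the aryl hydrocarbon receptor targets was 0.17 and 0.27. That of the cholesterol list was 0.0255 (adjusted p = 0.447) and 0.35 (adjusted p = 1.6e-07), and 0.36 without the 5 arrays with other tissue. Medians also moved for fatty acid synthesis (0.30 on slide 1, 0.28 without the 5 arrays), acute phase (-0.22 without the 5) and pericentral genes (-0.36 on slide 2). Slide 1 alone also ended the calls of pericentral (adjusted p = 0.972) and PPARa genes (0.0665), and slide 2 alone those of NRF2 targets (0.168) and fatty acid synthesis (0.357). Without the 5 arrays the call of PPARa genes ended (0.113), and without M 2 and 0.5M 4 that of pericentral genes (0.0934). Both genes lost their calls with median centring and Cyp2b2 also on slide 1 alone, while with the replicate number as a block 3 transcripts passed. Leaving out C 3 (adjusted p = 0.0334) or 0.5M 4 (0.0228) let Cyp2c6v1 pass.

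AhR against C asks what the mixture of dioxin-like compounds did. Cyp1a1 rose 5.50-fold (log2 2.46 ± 0.18, n = 4 arrays per group, adjusted p = 7.3e-06, higher in 4 of 4 arrays), and it was the single transcript to pass (495 at an unadjusted p under 0.05 by limma, against 657.3 by chance). Cyp1a2 stood at 0.21 with no AhR array above the highest C array, Cyp2b2 at 0.26 (3 of 4 arrays), Nqo1 at 0.15, Cyp3a23-3a1 at 0.07 and Abcc3 at 0.24, none of which passed. Cyp1b1 was not well above background on any array of either group. Among the 10 smallest p-values after Cyp1a1 were the NAD synthesis enzyme Nampt (-0.43), the mitochondrial carrier Slc25a47 (0.91), Nfil3 (-0.57, 3 of 4 arrays), the antiviral adaptor Mavs (-0.32), Herpud1 of the unfolded protein response (0.57) and the signalling inhibitor Smad7 (0.45). Kif7, Rpf2 and Entpd5 (0.34, -0.33 and 0.51) complete them. All of these had an adjusted p of 1.00, and those not given as 3 of 4 arrays had 4 of 4 beyond C.

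Targets of the aryl hydrocarbon receptor were called as a list in AhR, with a median of 0.16, 6 of 10 members higher and 1 member past the threshold, over all transcripts and adjusted over the list alone (adjusted p = 0.0131; adjusted p = 0.315 with an estimated correlation). Within slide 1 their median was 0.0370 (adjusted p = 0.485) and within slide 2 0.23 (adjusted p = 6.0e-04). CAR and PXR targets were not called (median 0.13, adjusted p = 0.303). Higher in AhR were cholesterol synthesis genes (22 of 23 members, median 0.23, adjusted p = 6.4e-07; adjusted p = 0.477 with an estimated correlation), fatty acid synthesis genes (14 of 16, 0.22, adjusted p = 0.00233), NRF2 targets (13 of 17, 0.12, adjusted p = 0.0113) and bile acid genes (12 of 17, 0.12, adjusted p = 0.0271), each also at 0.477 with an estimated correlation. Lower were acute phase genes (16 of 20 members, -0.11, adjusted p = 0.0271; adjusted p = 0.716 with an estimated correlation) and cell cycle genes (20 of 24, -0.10, adjusted p = 0.0152; 0.783 with it). Within slide 1 the cholesterol list had a median of -0.0597 (adjusted p = 0.976), and within slide 2 of 0.51 (adjusted p = 2.0e-15). Medians also moved for fatty acid synthesis (0.14 on slide 1), bile acid (0.23 on slide 2) and acute phase genes (-0.19 without the 5 arrays with other tissue). Bile acid genes (median 0.0734, mean -0.0141, adjusted p = 0.906), NRF2 targets (0.240) and acute phase genes (0.312) were not called on slide 1 either, nor fatty acid synthesis (0.197) and cell cycle genes (0.128) on slide 2. Cell cycle genes also lost their call without the 5 arrays with other tissue (0.132). No call among the 7 held with an estimated correlation or on both slides, and camera did not call 21 lists (adjusted p 0.117 to 0.988). Members with the smallest p in the 7 lists included Hmgcs1 of cholesterol synthesis (0.46), Acaca of fatty acid synthesis (0.22), the bile acid repressor Nr0b2 (0.68), the chemokine Cxcl1 (-0.45), Gsta3 (0.44) and the reductase Akr7a3 (0.58), none of which passed.

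Within slide 1 and slide 2 the difference of Cyp1a1 between AhR and C was 2.28 ± 0.30 and 2.64 ± 0.14. Its call was lost with median centring and on slide 1 alone, and the count stayed at 1 with the replicate number as a block.

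Among the exposed groups, M against 0.5M asks what doubling the dose added. Ceacam4 (3.71-fold, log2 1.89 ± 0.18, n = 4 arrays per group, adjusted p = 1.9e-04) and Cyp2c7 (3.03-fold, 1.597 ± 0.20, adjusted p = 0.00467) were higher in M, in 4 of 4 arrays each. Cyp2b2 (1.29, adjusted p = 0.0801), Cyp1a2 (0.91, adjusted p = 0.145) and Cyp2c6v1 (0.86, adjusted p = 0.198) did not pass. Cyp1a1 (0.84, adjusted p = 0.270), Gsta4 (0.59, adjusted p = 0.270) and Cyp3a23-3a1 (0.64, adjusted p = 0.449) did not either. Neither did A2m (-0.73), the glyoxylate enzyme Agxt (-0.56) and Nifk (0.43), at an adjusted p of 0.270 each, nor Cyp1b1 (0.60), Nqo1 (0.41) and Abcc3 (0.07). No transcript was lower in M by limma, with 888 at an unadjusted p under 0.05 in either direction. As lists, aryl hydrocarbon receptor targets (10 of 10 members, median 0.27, adjusted p = 4.2e-06) and CAR and PXR targets (15 of 17, 0.43, adjusted p = 9.8e-08) were higher in M. Adjusted over the list alone 4 and 6 members passed, and over all transcripts none. Both calls held with an estimated correlation (adjusted p = 0.0125 and 0.0309). Cholesterol synthesis genes were lower in M than in 0.5M (22 of 23 members, median -0.28, adjusted p = 2.8e-09; adjusted p = 0.326 with an estimated correlation), as were fatty acid synthesis genes (12 of 16, -0.24, adjusted p = 1.0e-04; 0.253 with it) and periportal genes (10 of 10, -0.20, adjusted p = 7.3e-04; 0.139 with it). Pericentral genes (9 of 9, 0.18, adjusted p = 0.0279; 0.375 with it) and macrophage markers (11 of 12, 0.12, adjusted p = 0.0313; 0.746 with it) were higher. Without the 5 arrays with other tissue the calls of macrophage markers (median -0.0410, adjusted p = 0.960) and pericentral genes (0.430) ended, and the median of the cholesterol list was -0.51. Slide 1 alone ended the same 2 calls (0.448 and 0.732), as did leaving out M 2 and 0.5M 4 (0.355 and 0.330) or M 1 and AhR 2 (0.205 and 0.0729). Camera did not call the remaining 21 lists (adjusted p 0.0725 to 0.925).

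Within slide 1 and slide 2 the difference between M and 0.5M was 1.497 and 2.28 for Ceacam4 and 1.61 and 1.58 for Cyp2c7, and the median of the cholesterol list was -0.22 and -0.41. The median of the aryl hydrocarbon receptor targets was 0.17 on slide 1, that of macrophage markers 0.18 on slide 2, and that of periportal genes -0.32 on slide 2 and -0.30 without M 2 and 0.5M 4. The count of 2 became 7 with the replicate number as a block or with Cy5 alone, 4 without M 2 and 0 with median centring or on slide 1 alone. The call of Cyp2c7 ended without the 5 arrays with other tissue. There its log2 ratios in M 3 and M 4 (-2.365 and -3.023) still lay above those in 0.5M 1, 0.5M 2 and 0.5M 3 (-4.268, -3.884 and -4.058). Without M 2 alone, Cyp2b2 (adjusted p = 1.2e-04) and Gsta4 (0.0491) passed.

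M against AhR and 0.5M against AhR ask how the mixture differed from the separate mixture of dioxin-like compounds. Their doses were not matched, so differences in composition and in dose cannot be told apart. In M, Cyp2b2 was 7.44-fold (log2 2.90, adjusted p = 8.3e-06), Ceacam4 4.53-fold (2.18, adjusted p = 1.3e-05) and Cyp1a1 4.35-fold (2.12, adjusted p = 2.0e-05) above AhR, each in 4 of 4 arrays. Cyp2c6v1 was 3.92-fold (1.97, adjusted p = 2.0e-05) and Cyp1a2 2.93-fold (1.55, adjusted p = 1.5e-04) above AhR, also in 4 of 4 arrays. Cyp3a23-3a1 (1.01, adjusted p = 0.0178) and Cyp1b1 (0.90, 1.83-fold as a bound for the dim AhR signal, adjusted p = 0.0217) were also higher. A2m (-1.22, adjusted p = 0.00183), Cyp17a1 (-0.83, adjusted p = 0.0136), the sterol sensor Scap (-0.60, adjusted p = 0.0300) and Slc16a11 (-0.54, adjusted p = 0.0366) were lower in M, in 4 of 4 arrays. Nqo1 (0.74, adjusted p = 0.180) and Abcc3 (0.20, adjusted p = 0.696) did not pass. In all, 26 transcripts were higher and 9 lower. In 0.5M, Cyp2b2 was 3.04-fold (1.61, adjusted p = 0.0227), Cyp1a1 2.44-fold (1.28, adjusted p = 0.0227) and Cyp2c6v1 2.15-fold (1.11, adjusted p = 0.0457) above AhR, in 4 of 4 arrays. No other transcript passed, and none was lower by limma (1189 at an unadjusted p under 0.05). The growth factor Vegfa (-0.70, adjusted p = 0.156) and the Wnt co-receptor Lrp6 (-0.47, adjusted p = 0.260) were among those that came next. Smad7 (-0.55), Arnt2 (-0.42), Osbpl11 (-0.40) and Ctnnal1 (-0.56) followed at 0.271 each. Other probes of Vegfa and Lrp6 differed from these.

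Aryl hydrocarbon receptor targets were higher in M than in AhR (4 of 10 passed, 5 adjusted over the list alone, median 0.47, adjusted p = 9.2e-12). They were also higher in 0.5M than in AhR (1 and 2, median 0.20, adjusted p = 1.6e-04). Both calls held with an estimated correlation (adjusted p = 6.1e-04 and 0.0357). CAR and PXR targets were higher in M (5 of 17, 10 adjusted over the list alone, median 0.62, adjusted p = 2.4e-17) and in 0.5M (2 and 4, median 0.35, adjusted p = 1.4e-06). These calls held with it too (adjusted p = 0.00113 and 0.0464). Gsta4 was the NRF2 target that passed in M, over all transcripts and adjusted over the list alone (list median 0.19, adjusted p = 0.00915; adjusted p = 0.323 with an estimated correlation). Cholesterol synthesis genes were lower in M than in AhR in 23 of 23 members (median -0.32, adjusted p = 5.3e-09; adjusted p = 0.278 with an estimated correlation), and fatty acid synthesis genes in 13 of 16 (-0.28, adjusted p = 0.0018; 0.278 with it). PPARa genes (median -0.11, adjusted p = 0.0193; 0.307 with it) and genes of glucose metabolism (-0.08, adjusted p = 0.0417; 0.222 with it) were lower in M too. So were glucocorticoid-responsive (-0.10, adjusted p = 0.0169; 0.0976 with it) and periportal genes (-0.22, adjusted p = 0.00915; 0.222 with it). In 0.5M, PPARa genes (-0.10, adjusted p = 4.7e-04; 0.181 with it) and macrophage markers (-0.16, adjusted p = 0.00994; 0.672 with it) were lower and cell cycle genes (0.11, adjusted p = 0.0270; 0.906 with it) higher than in AhR. The macrophage median was 0.11 on slide 1 alone (adjusted p = 0.0753) and -0.51 on slide 2 alone. Camera did not call the other 19 lists in M (adjusted p 0.0791 to 0.968) and 23 in 0.5M (0.0897 to 0.988).

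Within slide 1 and slide 2 the difference between M and AhR was 2.86 and 2.93 for Cyp2b2, 2.02 and 2.23 for Cyp1a1 and -1.56 and -0.89 for A2m. That between 0.5M and AhR was 1.81 and 1.40 for Cyp2b2, 1.47 and 1.10 for Cyp1a1 and 1.22 and 0.99 for Cyp2c6v1. The median of the cholesterol list in M against AhR was -0.13 (adjusted p = 0.0572) and -0.58 (adjusted p = 7.6e-13). In 0.5M the median of the CAR and PXR targets was 0.22 on slide 2 or without the 5 arrays with other tissue and 0.21 without M 2 and 0.5M 4. There, that of the aryl hydrocarbon receptor targets was 0.13 and that of PPARa genes -0.18 on slide 2, and that of cell cycle genes 0.25 on slide 1, 0.23 without the 5 arrays and 0.19 without M 2 and 0.5M 4. In M, glucocorticoid-responsive genes had a median of -0.22 on slide 2, -0.16 without M 2 and 0.5M 4 and -0.0601 without M 1 and AhR 2. Without the latter, PPARa genes had -0.18 and genes of glucose metabolism -0.26 (-0.22 without the 5). Slide 1 alone also ended the calls of NRF2 targets, periportal (0.0918 each), glucocorticoid-responsive (0.119) and PPARa genes (0.458) in M, and slide 2 alone those of glucose metabolism in M (0.175) and of cell cycle genes in 0.5M (0.644). Without the 5 arrays with other tissue the macrophage call in 0.5M ended (0.0672). Without M 2 and 0.5M 4 the calls of PPARa genes (0.0539) and glucose metabolism (0.0816) in M and of macrophage markers in 0.5M (0.148) ended, and without M 1 and AhR 2 that of cell cycle genes in 0.5M (0.0509). The means of these lists were then -0.0923, -0.127, -0.116 and 0.117, against -0.100, -0.143, -0.178 and 0.120 with all arrays. The count of 35 in M became 30 with the replicate number as a block, 19 without the 5 arrays with other tissue, 10 without AhR 4, 12 without M 3, 13 without M 4, 16 without AhR 3 and 18 without M 1. Single arrays ended the calls of Cyp17a1 (AhR 4 or M 3, adjusted p up to 0.0761), Cyp3a23-3a1 (5 of 8 arrays, up to 0.0853), Cyp1b1 (5, up to 0.102), Slc16a11 (7, up to 0.120) and Scap (6, up to 0.143). The count of 3 in 0.5M became 0 without 0.5M 1, 0.5M 2, 0.5M 3, AhR 1, AhR 3 or AhR 4 (adjusted p of Cyp2b2 up to 0.152, of Cyp1a1 up to 0.152 and of Cyp2c6v1 up to 0.242) and was 5 with the block.

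The doses 0, 0.5 and 1.0 mg/kg/day give a graded series. All 42 transcripts that passed in M against C lay in 0.5M between C and M, and 32 of them had an unadjusted p under 0.05 in 0.5M. The 42 were chosen for their difference in M, and 0.5M and AhR are set against the same C arrays. With an unchanged group simulated against such controls, 58.1% of the genes chosen lay in the same direction (95% of 1000 simulations from 23.3% to 88.2%), 57.9% between C and M, and 7.99% at an unadjusted p under 0.05 (0% to 32.5%). Summed over the 42, the log2 differences in 0.5M came to 49.2% of those in M (54.1%, 57.5%, 49.6% and 35.6% by array, SD 9.65, n = 4), against 3.13% (-8.46% to 15.02%) in the simulated unchanged group. With 42 genes chosen against 2 C arrays and measured against the other 2, the sum was 45.2% (39.4% to 49.6% over 6 divisions), and 35 to 40 of the 42 lay on the same side of C in 0.5M as in M. Cyp1a1 was the single transcript that departed from a straight line on the log2 scale (by 1.45 ± 0.16, adjusted p = 0.00151; 717 transcripts at an unadjusted p under 0.05). Unlogged, its 13.4-fold level in 0.5M lay near the 12.5-fold of a straight line between C and M. Ceacam4 (-0.69, adjusted p = 0.541) and Cyp2c7 (-0.64, adjusted p = 0.900) lay below the line without passing. In AhR the summed difference was 16.9% of that in M, above the simulated range, and 34 of the 42 lay in the same direction, within it. Without Cyp1a1 the sums were 45.9% in 0.5M and 13.2% in AhR, against a simulated range of -8.98% to 16.7%. With divided controls the sum in AhR was 10.9% (0.791% to 20.0%), with 13 to 34 of 42 in the same direction. Without M 2 the departing transcripts were 2, and with the 5 arrays with other tissue left out the departure of Cyp1a1 was 1.31 ± 0.21 (adjusted p = 0.179) and Ceacam4 alone passed (-0.91, adjusted p = 0.0322).

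**Figure D4:**
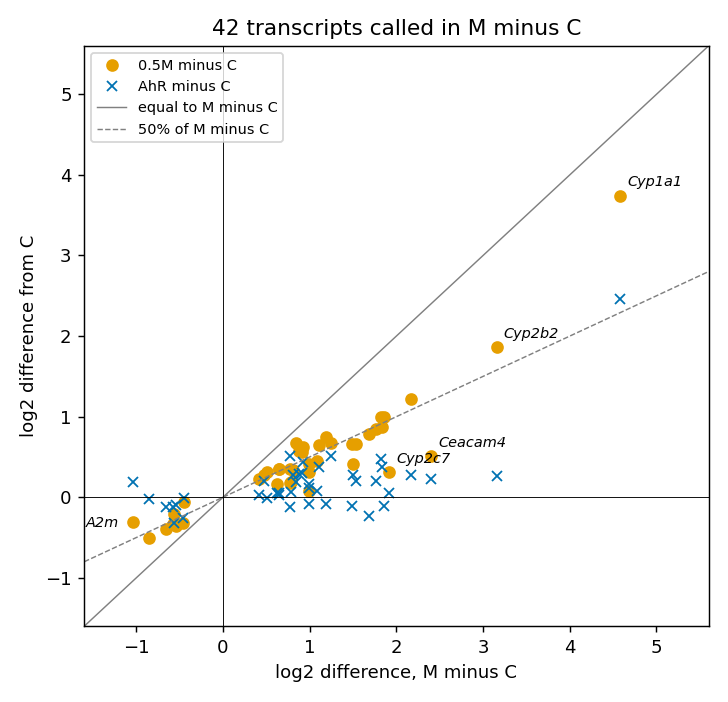
Log2 difference from C in 0.5M (circles) and AhR (crosses) against that in M for the 42 transcripts called in M against C; the solid line marks equal differences and the dashed line 50%. All 42 circles lie between 0 and the solid line, with Cyp1a1 at 4.58 in M and 3.74 in 0.5M.

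Across all 13146 transcripts the differences from C correlated between M and 0.5M (Pearson r = 0.652 across genes, same sign in 68.7%), between M and AhR (0.392, 63.6%) and between 0.5M and AhR (0.317, 60.1%). These differences share the 4 C arrays, and genes are not independent replicates. With unchanged groups simulated against a shared control group, r averaged 0.474 (95% of 1000 simulations from 0.0381 to 0.826). All 3 values lay within this range, which is too wide to decide what shared controls alone give. With the controls divided between the comparisons, r between M and 0.5M was 0.343 (0.205 to 0.444 over 3 divisions). It was 0.0619 (-0.0732 to 0.139) between M and AhR and -0.0291 (-0.241 to 0.102) between 0.5M and AhR. The spread that unchanged groups give with divided controls was not simulated. Whether shared C arrays account for all of r between M and 0.5M is therefore not settled. With shared controls, leaving out M 2 and 0.5M 4, the arrays with muscle transcripts, gave 0.515 between M and 0.5M. This was not combined with divided controls. Cyp1a1 and Cyp2b2 passed in both M and 0.5M against C, and Cyp1a1 in AhR as well.

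Camera called 14 lists in no comparison. Of these, 8 were metallothionein and heat shock (9 measured genes, lowest adjusted p 0.584), thyroid hormone axis (11, 0.626), male-biased (11, 0.161) and female-biased liver genes (9, 0.398), circadian clock (13, 0.0791), DNA methylation and one-carbon metabolism (10, 0.308), unfolded protein response (17, 0.140), and fetal liver genes (9, 0.242). The others were markers of endothelium (6, 0.481), stellate cells and fibroblasts (12, 0.129), cholangiocytes (5, 0.242), red cells and granulocytes (9, 0.338), lymphocytes (7, 0.227) and pancreas and fat (5, 0.679). The mixed test of fry called the female-biased genes in M against C (adjusted p = 1.6e-06), against 0.5M (4.8e-05) and against AhR (2.4e-06). Of the 41 list calls by camera over the 6 comparisons, 17 held on each slide alone. The lists were written to fit the tissue and the treatment, and of 469 members 367 were measured.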

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

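The tests of other tissue, of the reference channel, of an effect on muscle genes and of the clock phase, the marker lists behind them and the splits within slides were chosen after the results were seen; the other splits of the samples and the test of shared controls were not. A sample was singled out when its gap to the nearest array of its group, divided by the range of the 4 arrays, passed the 95% critical value of Dixon's test, which chance gives in about 1 of 20 groups. This held for 24 of 456 tests of genes (22.8 by chance), 0 of 8 tests of array quality and 12 of 44 tests of marker lists (2.2 by chance).

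Muscle transcripts were high in M 2 and 0.5M 4: 23 of 24 skeletal muscle markers (1 of them well above background on all 16 arrays), 5 of 7 of heart and 6 of 8 of smooth muscle lay above all 14 other arrays in both, against 0.833% by chance, with Myl11 at 3.696 and 3.740 (at most -1.73 elsewhere) and Ckm at 3.13 and 3.52. The 0.833% holds for a gene and a pair of arrays fixed beforehand, and this pair was picked for its muscle transcripts. A dimmer reference channel is argued against by Cy3, which was not lower at these probes (median difference 0.28, against 4.58 in Cy5), and an effect of the mixture on muscle genes in liver by the other 6 M and 0.5M arrays, which exceeded C by 0.14 (SD 0.08) in the median. A candidate source is RNA of muscle with adjoining squamous epithelium: 66.7% of 9 squamous markers (4 of 5 shared with skin, 2 of 4 of oesophagus and mouth) lay above all other arrays in both, with Krt15 at 3.64 and 3.21, but 0 of 4 markers of cornified skin, 0 of 7 of intestine and stomach, 0 of 6 of blood (median -0.52) and 0 of 20 of hepatocytes (-0.21) did. Krt1 of cornified skin stood at 2.105 in M 2 alone (at most 0.0480 elsewhere), so skin stays open as its site. How such RNA entered stays open, and no sorting step would have removed it. The ratio of gap to range was 0.880 for skeletal muscle, 0.920 for heart, 0.854 for smooth muscle, 0.872 and 0.960 for the squamous lists and 0.947 for hepatocyte markers (lower) in 0.5M 4, and 0.855 for heart, 0.904 for smooth muscle and 0.847 for oesophagus and mouth in M 2.

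Pancreas transcripts were high in M 1 and AhR 2 and fat transcripts in C 2. At these probes Cy3 was not lower by the amount needed (median differences of 0.0164 and -0.18), which argues against a dimmer reference channel. Pancreatic RNA is a candidate source in M 1 and AhR 2, where 75% of 12 markers (6 of them also in the fixed lists, 1 well above background on all arrays) lay above all 14 other arrays, with Ctrb1 at 3.05 and 1.18 and Prss1 at 2.38 and 1.89. Brown fat RNA is one in C 2, where 100% of 6 markers (3 also in the fixed lists) lay above all others and Ucp1 of brown fat stood at 3.33. Both tissues sit in more than 1 group or in C, so no effect of exposure was tested, and the ratios were 0.994 for pancreas markers in M 1, 0.989 and 0.835 for Ctrb1 in M 1 and AhR 2, and 0.838 for fat and 0.863 for oesophagus and mouth markers in C 2.

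Nfil3, a repressor of clock genes, was lower in the 12 exposed arrays than in C by a mean log2 difference of -0.61 (-0.54 on slide 1 and -0.68 on slide 2). It was picked for this pattern and passed in no comparison. Other tissue RNA in 5 arrays is argued against, since the mean of the 3 differences was -0.58 without them. C pups sampled at another phase of the clock remain a possible explanation: a score of 5 clock genes minus 4 that peak at the opposite phase was -0.95 in C and -0.50 in the others (exact permutation p = 0.0485 over 784 sets of arrays), with Dbp at 0.78, Tef at 0.25, Usp2 at 0.0812, Per3 at 0.0646 and Nr1d1 at 0.0555, against Cry1 at -0.44, Bmal1 at -0.31, Clock at -0.0912 and Npas2, which went the other way, at 0.0308 (0.16 on slide 1). On slide 2, Per3 (-0.0310) and Nr1d1 (-0.0299) went the other way too. Chance values of the shared controls may also account for it, as 27.6% of such sets separated at least the 23 transcripts that C separated from the other arrays. An effect common to the 3 exposures stays open and was not tested apart from these.

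In C, the array apart from the other 3 was C 3 for Ceacam4 (ratio 0.840), C 4 for Gsta4 (0.967), C 2 for Me1 (0.853) and C 1 for Patz1 (0.845). In 0.5M, it was 0.5M 1 for Cyp1a1 (0.872; log2 ratio 2.69 against a mean of 1.90), Abcc3 (0.865), Ces1c (0.861) and Nkg7 (0.845), 0.5M 2 for Rhbg (0.854) and Osbpl11 (0.845), 0.5M 3 for Cxcl1 (0.833), and 0.5M 4 for Mavs (0.947) and the pancreas gene Cpa1 (0.937). In M, it was M 4 for Lyplal1 (0.917), Agxt (0.907) and Spp1 (0.850) and M 2 for Scap (0.873; -0.52 against a mean of -0.09). In AhR, it was AhR 2 for Slc30a1 (0.951), AhR 4 for Ube2c (0.876) and Ugt1a6 (0.855), and AhR 1 for Cyp2a2 (0.869; -2.999 against a mean of -4.06) and Ceacam4 (0.848).

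Other splits of the arrays were tried for every count. For the counts of genes in the 6 pairwise comparisons, only 1 of 35 splits, the real one, gave as many: 42 in M against C (highest other 8), 2 in 0.5M against C (1), 1 in AhR against C (0), 2 in M against 0.5M (1), 35 in M against AhR (1) and 3 in 0.5M against AhR (1). Some of these splits exchange arrays between the 2 slides, which differed in 1053 transcripts, so they do not exclude chance. The 18 of these splits that keep 2 arrays of each group on each slide are too few for a share under 5%; in them the highest other count was 8 in M against C, 1 in 0.5M against AhR and 0 in the other 4. For the F-test, the regroupings argue against chance for the count of 23 genes (1 of 100, the real one, highest other 14, and within slides 1 of 100, highest other 9). They cover the count and not each gene, and would not hold if arrays shared litters. For the 1 gene departing from a straight line over the doses, chance cannot be excluded (5 of 100, highest other 4, and within slides 5 of 100, highest other 2). For lists called with the preset correlation it cannot be excluded: as many came from 18 of 35 splits in M against C (5, highest other 8), 3 in 0.5M against C (8, 9), 6 in AhR against C (7, 11), 6 in M against 0.5M (7, 9), 4 in M against AhR (9, 12) and 12 in 0.5M against AhR (5, 7). For the 2 lists called with an estimated correlation in 5 comparisons, 1 of 35 splits, the real one, gave as many (highest other 1, and 0 in 0.5M against AhR). Chance is not excluded here either, as the 18 splits within slides are again too few.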

How the results depend on the processing

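Leaving out arrays with other tissue, the list tests within slides and the alternatives for the dose and shared responses were chosen after seeing the data; the other alternatives were not. No transcript called in a comparison, with or without a symbol, changed direction under an alternative that fitted it (0 of 1168 values for the 42 of M against C and 0 of 972 for the 35 of M against AhR). Many alternatives only left arrays out or changed the error model. As groups did not overlap for 40 of the 42 in M against C, a direction could hardly change there, so this is a weak test. Over the alternatives, called named genes kept their calls in 592 of 836 values for M against C, 53 of 56 for 0.5M against C, 26 of 28 for AhR against C, 48 of 55 for M against 0.5M, 230 of 306 for M against AhR and 44 of 84 for 0.5M against AhR. Cyp1a1 in M against C kept its call under 28 of 28 (log2 4.16 to 5.403). The count of genes ranged over its alternatives from 1 to 83 in M against C (20 of 30 within 1.5 times), 0 to 3 in 0.5M against C (28 of 30), 0 to 1 in AhR against C (28 of 30), 0 to 7 in M against 0.5M (20 of 30), 0 to 64 in M against AhR (16 of 30), 0 to 5 in 0.5M against AhR (17 of 30) and 0 to 35 for any difference among the groups (28 of 36). The summed dose ratio stayed within 41.6% to 57.2%, with 45.2% for genes chosen against 2 C arrays and measured against the other 2. Signal over background limits what was tested: 14524 of 30367 probes passed the filter, and nothing is said of the others. Fewer probes on average stood well above background on slide 1 than on slide 2, and whether this lowered its counts was not tested.

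Moved counts of genes were these. With the replicate number as a block: 7 in M against 0.5M and 5 in 0.5M against AhR. With the scanner's log ratios: 20 in M against C, 19 in M against AhR, 0 in 0.5M against AhR and 15 for any difference. With median centring: 1 in M against C and 0 in each other comparison, for any difference and for departure from a straight line. With Cy5 alone: 7 in M against 0.5M, 20 in M against AhR and 1 in 0.5M against AhR. With probes well above background on 16 arrays: 1 in M against 0.5M. With array weights: 66 in M against C, 4 in M against 0.5M and 64 in M against AhR. At an adjusted p under 0.10, a wider threshold by construction: 83 in M against C, 4 in M against 0.5M and 35 for any difference. With fewer arrays in the model, the counts moved as follows. Slide 1 alone: 4 in M against C, 1 in 0.5M against C, 0 in the other 4 comparisons, 1 for any difference and 0 for departure. Slide 2 alone: 7 in M against C, 4 in M against 0.5M, 13 in M against AhR and 7 for any difference. Only the 2 groups compared: 19 in M against AhR and 1 in 0.5M against AhR. Without M 1 and AhR 2: 20 and 1 in these. Without the 5 arrays with other tissue: 4 in M against 0.5M, 19 in M against AhR and 15 for any difference. Without M 2 and 0.5M 4: 2 for departure. With each array left out in turn: 22 (without C 4 or M 3; 25 without C 1, 27 without M 1) to 50 in M against C, 2 to 4 (without M 2) in M against 0.5M, 10 (without AhR 4; 12 without M 3, 13 without M 4, 16 without AhR 3, 18 without M 1) to 31 in M against AhR, 0 to 3 in 0.5M against AhR (0 without 0.5M 1, 0.5M 2, 0.5M 3, AhR 1, AhR 3 or AhR 4), 11 (without M 3 or M 4) to 30 for any difference and 1 to 2 (without M 2) for departure. Beside fewer arrays and the wider threshold, the cause was not tested.

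Of lists, an estimated correlation left 2 in every comparison but AhR against C, which had 0. Directional fry called 2 in 0.5M against C, M against 0.5M and 0.5M against AhR, 3 in M against AhR and 1 in AhR against C; mixed fry called 2 in 0.5M against C, 1 in AhR against C, 4 in M against 0.5M and 3 in 0.5M against AhR. Median centring gave 9 in M against C and 2 in 0.5M against AhR, and Cy5 alone 5 in 0.5M against C. Slide 1 alone gave 5 in 0.5M against C, 2 in AhR against C and 8 in 0.5M against AhR, and slide 2 alone 11 in M against C and 9 in 0.5M against AhR. Without M 1 and AhR 2 there were 9 in M against C and 14 in M against AhR, and without the 5 arrays 8 in M against C. Of 41 list calls over the 6 comparisons, 18 ended on slide 1 alone, 6 on slide 2 alone, 5 without the 5 arrays, 7 without M 2 and 0.5M 4 and 3 without M 1 and AhR 2, and 16, 26, 14, 2 and 12 other lists were called there. The mean of macrophage markers turned to -0.0131 in M against 0.5M without the 5 arrays and to 0.13 in 0.5M against AhR on slide 1. The correlation across genes was 0.343, 0.0619 and -0.0291 for M and 0.5M, M and AhR, and 0.5M and AhR with divided controls, which removes the shared arrays. It was 0.515 for M and 0.5M without M 2 and 0.5M 4, and with each array left out 0.489 to 0.705, 0.275 to 0.480 and 0.254 to 0.470.

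Genes that had not passed and changed direction were these. With median centring: Hsp90aa1 (-0.12) and C1qb (-0.11) in M and Cyp3a23-3a1 (-0.00234) in AhR, each against C. With Cy5 alone: Ube2c (-0.00881) in 0.5M, and Cyp3a23-3a1 (-0.00978), Cdh5 (-0.0139) and Klf1 (0.0532) in AhR. On slide 1: Dnmt3a (0.0132) in 0.5M, Vsig4 (-0.0421), Cdh5 (-0.0376) and Krt19 (0.12) in AhR, and Abcc3 (-0.22) in M against 0.5M. On slide 2: Oit3 (0.0327) in M and Cyp3a23-3a1 (-0.24) in AhR. Without the 5 arrays: Tpx2 (0.00187) and Oit3 (0.11) in M. With 1 array left out, Cyp3a23-3a1 in AhR ranged from -0.11 (without C 1) to 0.16, Krt19 in AhR from -0.21 to 0.0184 (without AhR 3) and Abcc3 in M against 0.5M from -0.00287 (without M 3; -0.00101 without M 4) to 0.16. The cause was not tested.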

Other observations

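The genes named here were chosen after their values were seen. Of the genes with a symbol that rose in M against C, 13 have no value for it above, each with all 4 M arrays above all C arrays. Enzymes that attach glucuronic acid or glutathione to foreign compounds were among them: Ugt2b1 (2.28-fold, adjusted p = 0.0261), Ugt2b15 (1.54-fold, adjusted p = 0.0261) and Gstm2 (1.99-fold, adjusted p = 0.0173). Others were the P450 Cyp2a3 (2.80-fold, adjusted p = 0.00788), Cyb5a (1.89-fold, adjusted p = 3.3e-04) and Pgrmc1 (1.38-fold, adjusted p = 0.0459), both of which bind haem and act with P450 enzymes, and the carboxylesterases Ces1c (1.84-fold, adjusted p = 0.0261) and Cesl1 (1.99-fold, adjusted p = 0.0373). The secreted protein gene Tsku (2.37-fold, adjusted p = 0.00838), the phosphatase of nucleotides Entpd5 (1.71-fold, adjusted p = 0.0187), Pbld1 (1.75-fold, adjusted p = 0.00119), Mmgt1 (1.42-fold, adjusted p = 0.00838) and Lyplal1 (1.33-fold, adjusted p = 0.0470) complete the list. The calls of Cyp2a3, Cyb5a, Tsku, Pbld1 and Mmgt1 held with each array left out in turn. Those of the others each ended without some single arrays: Gstm2 without C 1, M 1 or C 3 (adjusted p up to 0.0747), Ugt2b15 without M 1, M 2, C 2 or M 3 (0.0886), Ugt2b1 without C 1, C 3, M 3, M 4 or C 4 (0.110), Entpd5 without C 1, M 1, M 3, M 4 or C 4 (0.0936), Ces1c without M 1, C 2, C 3, M 3 or C 4 (0.114), Cesl1 without any but M 2 (0.177), Lyplal1 without any but C 3 (0.205) and Pgrmc1 without any of the 8 (0.182).

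Some lists whose members moved both ways in M against C, bile acid and female-biased genes among them, were called by the mixed test of fry and not by camera. Of 17 bile acid genes, 4 passed adjusted over the list alone (0 over all transcripts, adjusted p of the list 1.6e-05 by fry and 0.965 by camera): Cyp8b1, which makes cholic acid, at -0.59 and the bile acid receptor Nr1h4 at -0.42 were lower in M, and the repressor Nr0b2, a target of that receptor, at 0.95 and the uptake carrier Slco1b2 at 0.44 were higher. Another probe of Nr1h4 gave 0.07. Among genes with higher levels in female liver (adjusted p = 1.6e-06 by mixed fry), Cyp2a1 at 0.73 went up beside Cyp2c7, and Fmo1 at -0.44 and Sult2a6 at -0.23 went down beside Cyp17a1, none of these 3 past the threshold over all transcripts. Other probes of called genes differed in size: Cyp2b2 at 2.02 in M and 1.21 in 0.5M, Ugt1a6 at 0.75 and Ces1c at 0.49 in M against C.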
